A study of Mus musculus with 24 samples.

How the data were processed

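Polyadenylated RNA was measured by RNA sequencing in 24 samples of mouse embryonic stem cells and embryoid bodies, 3 samples for each of 8 groups formed by 2 genotypes and 4 days. Each sample's genotype, day and replicate number came from its title. Per the labels' protocols, libraries were stranded (dUTP method) and sequenced on an Illumina instrument, and per the submitters' processing notes FastQC, cutadapt, HISAT2 and StringTie were used with genome build mm10. Versions, settings and the gene annotation are not given in the sources used here. The authors deposited a gene table and a transcript table whose values are FPKM, per the file headers. FPKM divides fragments by transcript length and by the library's total, so a strongly expressed family such as the globins can lower the values of other genes.

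There were 14737 gene records and 30794 transcript records, all of type protein-coding, and in every record the highest of the 8 group means was at least 0.5. Noncoding genes, Carma among them, were therefore not analysed here, and the planned test of noncoding against coding genes among the calls was not run. Of 7586 genes with several listed transcripts, the median ratio of gene FPKM to the sum of transcript FPKM was 0.705, so the transcript values are not parts of the gene value. For 2537 of 6947 genes with 1 listed transcript both values were equal within 1e-05 in every sample. A symbol was shared by 2 records in 15 cases, and each record was tested. Depth is unknown: low values were searched for whole-read steps, but only 2 of 181 low genes shared the most frequent ratio between replicates. No interval or detection floor that needs a read count is given, and an exact 0 is called listed at 0.

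Values were used as log2(FPKM + 1) without further scaling. Genes with at least 1 FPKM in at least 3 of the 24 samples were tested, 13373 in all. A linear model with 1 mean per group (16 residual degrees of freedom) was fitted with limma 3.58.1 in R 4.3.3, with the trend of variance on mean expression, for 10 contrasts: 3 steps between consecutive wild type days, the genotype difference on each of 4 days, and the change of the genotype difference from d0 to d3, d6 and d10. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast, two-sided. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, and again with a correlation estimated from the data. Of 29 lists 28 had at least 3 tested members. The list of cardiovascular long noncoding RNAs had 1 tested gene of 23 symbols and was not tested. Of 660 list symbols 593 were in the gene table. The Carma locus took in records within 500 kb of Carma, Gata5 or the Mir1a-1 and Mir133a-2 host gene, as far as the files hold these.

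Groups, contrasts, tests, lists, named genes and alternatives were fixed before the data were examined, except where a choice is said to have been made later. Named genes were, per wild type step and genotype comparison, the 5 largest positive and 5 largest negative log2 changes among called genes with a mean of at least 5 FPKM in the higher group, no overlap between replicates and an ordinary symbol. To these came up to 4 called members of each list with the largest absolute change, the genes of the locus, 12 fixed single genes of which 11 were tested, and per change of the genotype difference the 3 largest each way without the condition on overlap. Some genes that this rule takes in are not reported here. Members named only to spell out a count of 5 or fewer were chosen after their values were seen.

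The alternatives were a pseudocount of 0.1, no filter beyond a value above 0, a filter at 5 FPKM, median-of-ratios and quantile normalization, a fit of only the groups compared, the replicate number as a block, sample quality weights, an absolute log2 change of at least 1, the estimated correlation, the transcript table for the locus, and leaving out each library of the groups compared. Leaving out chromosome 11, and leaving out replicate 1 of Carma3xpA/+ at d0 from the comparisons that do not contain it, were chosen after the data were seen. The model was tested on simulated data for the d3 genotype comparison with 13272 genes, of which 13040 were left unchanged. It called 40 of 67 genes changed by 0.5 (log2), 63 of 67 by 1 and 64 of 66 by 2. It also called all 32 members of 1 list changed by 1, that list alone, and 10 unchanged genes (4.78% of the 209 calls). Other splits of the 6 real libraries, which keep part of the difference, called up to 7 lists.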

Results

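Polyadenylated RNA was profiled in mouse embryonic stem cells of strain 129/Sv and in their cardiac derivatives. Wild type cells were compared with cells of the genotype Carma3xpA/+. In the usual notation this means that 1 allele of Carma, a long noncoding RNA gene, carries a cassette of 3 polyadenylation signals that ends transcription early. Embryonic stem cells were kept on mouse feeder fibroblasts with serum and LIF, and aggregation in hanging drops started their differentiation as embryoid bodies. Libraries came from undifferentiated cells (d0) and from embryoid bodies at d3, d6 and d10. With 2 genotypes, 4 days and 3 stated biological replicates there were 8 groups and 24 libraries. The labels do not say whether replicates came from separate clones or cultures, so the p-values measure the spread between these libraries. Values are FPKM, given as mean ± SD over the 3 libraries of a group, and every p is a Benjamini-Hochberg adjusted p from limma unless named otherwise. Counts of list members adjusted over the list alone are given where they differ from those over all genes. Fold values are ratios of group mean FPKM, whereas log2 changes are on the log2(FPKM + 1) scale and understate changes of low genes. Summed FPKM lay between 245274 and 306848 per library, and between 10667 and 11921 genes reached 1 FPKM. Pearson correlations across genes between replicates of a group ranged from 0.9541 to 0.9947, and genes are not independent replicates. Both lowest values, 0.9541 and 0.9586, belonged to replicate 1 of Carma3xpA/+ at d0, whereas replicates 2 and 3 of that group correlated at 0.9912.

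Carma lies beside the Mir1a-1 and Mir133a-2 host gene on chromosome 2, next to Gata5. Carma itself was not analysed here, so its level cannot serve as a check of the genotype labels. Among protein-coding genes within 500 kb of Gata5 (ENSMUSG00000015627.5, mm10 chromosome 2, 180325133 to 180334699), 19 were tested. Gata5, a cardiac and endodermal transcription factor, was near 0 at d0 and d3. It reached 10.2 ± 0.703 FPKM in Carma3xpA/+ and 10.4 ± 1.14 in wild type at d6, a log2 difference of -0.02 ± 0.12 (SE, adjusted p = 0.97). At d10 Gata5 was higher in Carma3xpA/+, at 2.84 ± 0.900 against 1.17 ± 0.132 FPKM (log2 difference 0.80 ± 0.12, adjusted p = 0.000113). Lama5, a laminin chain gene, was lower in Carma3xpA/+ at d10 (4.74 ± 0.648 against 8.45 ± 0.694 FPKM, adjusted p = 0.0012) and at d0 (13.3 ± 3.49 against 21.3 ± 1.77, adjusted p = 0.00269). Dido1 was also lower at d0, by -0.70 on the log2 scale (adjusted p = 0.0015). Each of these calls held without any 1 library of the groups compared. The d0 calls of Psma7 (0.43, adjusted p = 0.0304) and Gid8 (-0.32, adjusted p = 0.0306) did not. Both were lost without Carma3xpA/+ replicate 1 (0.162 and 0.111) or wild type replicates 1 (0.0951 and 0.191) or 2 (0.0698 and 0.0895). Psma7 was also lost without wild type replicate 3 (0.0571) and Gid8 without Carma3xpA/+ replicate 3 (0.0511). In a fit of only the d0 libraries no d0 locus call held. limma called 4 of 19 locus genes at d0 and 2 at d10, shares similar to 2516 and 1453 of all 13373. At d3 and d6 it called 0, with 0 and 1 at an unadjusted p under 0.05. Adjusted over the list alone, the counts were 7, 0, 0 and 4 at d0, d3, d6 and d10.

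The wild type series describes how these cells left the undifferentiated state. Between d0 and d3 the pluripotency list fell and the formative epiblast and primitive streak lists rose, at the preset correlation only. Klf4, a naive pluripotency factor, fell 57.5-fold from 82.7 ± 5.95 to 1.44 ± 0.306 FPKM, and Tfcp2l1 fell 17.9-fold. Nanog fell 1.72-fold, from 278 ± 19.2 to 162 ± 14.5 FPKM (adjusted p = 0.000896), whereas Pou5f1, which encodes Oct4, measured 243 ± 14.6 at d0 and 327 ± 12.3 at d3 (adjusted p = 0.149, and 0.00132 in a fit of only these 6 libraries). Of 28 pluripotency genes, 24 fell and 1 rose (median log2 change -1.39, adjusted p = 1.2e-09, and adjusted p = 0.0511 with an estimated correlation). Of 15 formative and primed epiblast genes, 11 rose and 2 fell (median 1.61, adjusted p = 0.000249, and adjusted p = 0.298 with an estimated correlation). They included Fgf5 (29.2-fold to 64.6 ± 2.12 FPKM), Otx2 (9.58-fold), the de novo methyltransferase gene Dnmt3b (7.78-fold) and Cer1, a secreted Nodal and BMP antagonist, which reached 32.0 ± 13.5 FPKM from 0.159 ± 0.140. Of 24 primitive streak and early mesoderm genes, 16 rose and 4 fell (median 1.08, adjusted p = 0.00366, and adjusted p = 0.653 with an estimated correlation). Eomes rose 14.0-fold to 95.8 ± 6.12 FPKM, Mixl1 rose 13.0-fold, Gsc rose 19.9-fold and Mesp1, the marker of cardiac mesoderm, rose 31.6-fold to 18.3 ± 10.3. T, which encodes Brachyury, rose 2.16-fold from 42.9 ± 12.7 to 92.5 ± 10.4 (adjusted p = 0.0292). Of 21 Wnt target genes, 10 rose and 2 fell (median 0.58, adjusted p = 0.0481, and adjusted p = 0.729 with an estimated correlation). Both the rise of T and the Wnt list call were lost without wild type d0 replicate 3 (adjusted p = 0.136 and 0.0981), d3 replicate 2 (0.0612 and 0.0558) or d3 replicate 3 (0.0798 and 0.0573).

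Other groups fell over the same interval. Of 19 genes of the 2-cell-like state, a rare totipotent-like state of embryonic stem cell cultures, 19 fell (median -2.87, adjusted p = 3.1e-13, and adjusted p = 0.132 with an estimated correlation). Zscan4e fell 48.7-fold from 87.5 ± 1.05 FPKM, Zscan4f 37.2-fold and Zscan4b 50.2-fold. These genes are near-identical copies, so how reads were divided among them is uncertain. Immediate early and heat shock genes fell in 18 of 20 cases and 1 rose (median -2.41, adjusted p = 1.1e-10, and adjusted p = 0.0511 with an estimated correlation). Fos fell 62.5-fold from 94.5 ± 1.62 to 1.51 ± 0.493 FPKM and Egr1 fell 17.4-fold. Of 20 p53 and apoptosis genes, 18 fell and 1 rose (median -0.93, adjusted p = 8.8e-07, and adjusted p = 0.0853 with an estimated correlation), with Plk2 down 7.84-fold. Glycolysis and hypoxia genes fell in 19 of 29 cases and 4 rose (median -0.95, adjusted p = 0.000146, and adjusted p = 0.4 with an estimated correlation), including the glucose transporter gene Slc2a3, down 5.89-fold. Germ cell genes fell in 13 of 14 cases (median -1.08, adjusted p = 1.6e-06, and adjusted p = 0.0511 with an estimated correlation). Fibroblast and feeder genes fell in 13 of 23 cases and 1 rose (median -0.53, adjusted p = 0.00191, and adjusted p = 0.388 with an estimated correlation). Col1a1 fell 21.2-fold from 13.1 ± 1.58 FPKM; the undifferentiated cells had been kept on feeder fibroblasts. Smooth muscle genes fell in 11 of 17 cases and 1 rose (median -0.62, adjusted p = 0.00223, and adjusted p = 0.314 with an estimated correlation), with Acta2 down 12.9-fold. BMP and TGF-beta targets fell in 12 of 22 cases and 1 rose (median -0.70, adjusted p = 0.00149, and adjusted p = 0.399 with an estimated correlation). Trophoblast genes fell in 11 of 14 cases (median -1.22, adjusted p = 0.00122, and adjusted p = 0.129 with an estimated correlation). Smaller shifts to lower values were called for 32 sarcomere genes (13 fell, 11 adjusted over the list alone, adjusted p = 0.0194), 8 skeletal myogenic genes (5 fell, adjusted p = 0.0226) and 23 unfolded protein response genes (12 fell and 3 rose, 4 rose adjusted over the list alone, adjusted p = 0.0215). With an estimated correlation their adjusted p were 0.729, 0.129 and 0.584, and quantile normalization ended the sarcomere call (0.0514). Rbpj, the DNA-binding partner of Notch, fell 3.52-fold to 9.05 ± 0.389 FPKM, while the 26 Notch genes were not called as a list (adjusted p = 0.126). In all, 7416 of 13373 genes changed, 3708 higher and 3708 lower (3194 and 4228 with median-of-ratios scaling, 4185 and 3367 after quantile normalization). None of the 16 lists called at the preset correlation passed with an estimated one, but without replicate 1 of Carma3xpA/+ at d0 5 did, the 2-cell-like (0.0126), stress, p53, germ cell and trophoblast lists (0.0497 each). 

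Between d3 and d6 globin genes had the largest log2 changes: Hbb-bh1 rose from 3.84 ± 4.27 to 1928 ± 641 FPKM and Hba-x from 1.12 ± 1.31 to 881 ± 291. Hba-a1 and Hba-a2, near-identical copies that share reads, reached 223 ± 80.5 and 231 ± 108 FPKM. Of 23 blood genes, 22 rose and 1 fell (median log2 change 3.08, adjusted p = 1.2e-13, and adjusted p = 0.0137 with an estimated correlation). Of 24 endothelial genes, 23 rose (median 3.19, adjusted p = 4.1e-14, and adjusted p = 0.0137 with an estimated correlation), with Cdh5 at 67.2 ± 8.79 FPKM from 0.103 ± 0.105 and Tie1 at 21.1 ± 3.68. Of 25 cardiac progenitor regulators, 23 rose (median 2.17, adjusted p = 1.8e-10, and adjusted p = 0.0586 with an estimated correlation). Nkx2-5 reached 9.57 ± 1.00 FPKM, Isl1 11.1 ± 1.10, Hand2 32.6 ± 3.19 and Hand1 65.9 ± 6.41. Sarcomere and calcium handling genes rose in 28 of 32 cases (median 2.56, adjusted p = 2.6e-13, and adjusted p = 0.0844 with an estimated correlation). The atrial light chain gene Myl7 rose to 422 ± 75.8 FPKM and cardiac actin Actc1 56.6-fold to 214 ± 23.9. Tnnt2 reached 21.6 ± 3.85 and Myh6 33.3 ± 2.94. Fibroblast genes rose in 21 of 23 cases and 1 fell (median 2.19, adjusted p = 5.2e-09, and adjusted p = 0.0586 with an estimated correlation), among them Postn (46.5 ± 23.4 FPKM) and Col1a1 (53.3 ± 26.7). Endoderm genes rose in 22 of 28 cases and 2 fell (median 1.23, adjusted p = 0.000134, and adjusted p = 0.454 with an estimated correlation), with Ttr at 82.3 ± 16.3 FPKM. Imprinted genes rose in 15 of 19 cases and 1 fell (median 1.92, adjusted p = 9.3e-05, and adjusted p = 0.282 with an estimated correlation), with Igf2 at 244 ± 10.7 FPKM.

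The pluripotency and streak lists fell over this interval, the latter at the preset correlation only. Pou5f1 fell 19.4-fold to 16.8 ± 1.04 FPKM and Nanog to 8.52 ± 1.11. Pluripotency genes fell in 24 of 28 cases and 2 rose (median -1.55, adjusted p = 1.2e-11, and adjusted p = 0.0197 with an estimated correlation). Formative genes fell in 14 of 15 cases (median -2.54, adjusted p = 5.2e-09, and adjusted p = 0.0586 with an estimated correlation). Streak genes fell in 16 of 24 cases and 4 rose, with 17 lower adjusted over the list alone (median -1.42, adjusted p = 0.000115, and adjusted p = 0.429 with an estimated correlation). Mixl1 fell to 0.482 ± 0.396 FPKM, Eomes 48.9-fold, Mesp1 30.0-fold and T 2.35-fold (adjusted p = 0.017). Cell cycle genes fell in 26 of 32 cases (median -0.53, adjusted p = 1.1e-08, and adjusted p = 0.0137 with an estimated correlation). Wnt targets fell in 13 of 21 cases and 6 rose, 7 adjusted over the list alone (median -1.05, adjusted p = 0.0161, and adjusted p = 0.502 with an estimated correlation). Germ cell genes fell in 11 of 14 cases and 2 rose (median -0.99, adjusted p = 0.000114, and adjusted p = 0.0628 with an estimated correlation), and 5 of 19 genes of the 2-cell-like state fell further (median -0.24, adjusted p = 0.0233, and adjusted p = 0.575 with an estimated correlation). Glycolysis genes rose in 21 of 29 cases and 1 fell (median 0.91, adjusted p = 0.000112, and adjusted p = 0.386 with an estimated correlation). Smooth muscle genes rose in 14 of 17 cases (median 0.93, adjusted p = 9.5e-05, and adjusted p = 0.127 with an estimated correlation). Notch genes rose in 18 of 26 cases and 3 fell, 5 adjusted over the list alone (median 0.75, adjusted p = 0.0131, and adjusted p = 0.464 with an estimated correlation). Unfolded protein response genes rose in 15 of 23 cases, with 1 lower adjusted over the list alone (median 0.87, adjusted p = 0.00145, and adjusted p = 0.356 with an estimated correlation). Over all genes, 4733 rose and 3305 fell, 8038 in total. That split depended on scaling, since quantile normalization gave 3524 higher and 4536 lower of 8060, and the median shift of all genes was 0.10 as deposited and -0.07 after quantile normalization. BMP targets, not called at 0.0765, and trophoblast genes, at 0.0984, were called without replicate 1 of Carma3xpA/+ at d0 (0.0442 and 0.0453), which enters the shared estimate of the spread. The fall of T was lost without wild type d3 replicate 3 (adjusted p = 0.0512), d6 replicate 2 (0.0514) or d6 replicate 3 (0.0582).

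Between d6 and d10 the blood and endothelial lists fell, and the fibroblast, endoderm and neuroectoderm lists rose at the preset correlation only. Hba-x fell 19.3-fold to 45.6 ± 12.7 FPKM and Hbb-bh1 14.1-fold to 137 ± 52.6. Of 23 blood genes, 19 fell and 3 rose (median log2 change -2.03, adjusted p = 3.1e-11, and adjusted p = 0.0278 with an estimated correlation). Of 24 endothelial genes, 22 fell, with 1 higher adjusted over the list alone (adjusted p = 1.3e-16, and adjusted p = 0.0189 with an estimated correlation). Kdr fell 10.4-fold, Plvap 11.4-fold and Cdh5 9.63-fold. Cardiac progenitor regulators fell in 16 of 25 cases and 1 rose (median -0.87, adjusted p = 4.6e-05, and adjusted p = 0.266 with an estimated correlation), with Nkx2-5 down 3.31-fold to 2.90 ± 0.541 FPKM and Isl1 2.80-fold. The sarcomere list was not called (15 of 32 higher, 6 lower, median 0.23, adjusted p = 0.0896), but it was without wild type d10 replicate 3 (0.00937). Tnnt2 measured 25.1 ± 4.40 FPKM at d10, Myh6 34.2 ± 6.20 and Actc1 179 ± 43.6 (adjusted p = 0.376, 0.92 and 0.448), and for Myh6 the log2 difference of 0.03 was -0.15 after quantile normalization, -0.07 without wild type d10 replicate 1, and -0.03 without d10 replicate 2 or without d6 replicate 2. Fibroblast genes rose in 16 of 23 cases, with 1 lower adjusted over the list alone (median 1.11, adjusted p = 1.8e-06, and adjusted p = 0.146 with an estimated correlation). The collagen crosslinking enzyme gene Lox rose 51.3-fold to 39.6 ± 8.92 FPKM and Dcn 28.5-fold. Smooth muscle genes rose in 8 of 17 cases and 2 fell (median 0.64, adjusted p = 0.00431, and adjusted p = 0.336 with an estimated correlation). Actg2, an enteric smooth muscle actin, rose from 0.836 ± 0.216 to 108 ± 4.99 FPKM. The macrophage lysozyme gene Lyz2 reached 72.7 ± 3.33 FPKM from under 2.

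Endoderm genes rose in 14 of 28 cases over this last interval (median 0.81, adjusted p = 0.000369, and adjusted p = 0.554 with an estimated correlation), with the alpha-fetoprotein gene Afp up 12.7-fold to 313 ± 95.1 FPKM. Neuroectoderm genes rose in 11 of 20 cases and 3 fell (median 0.91, adjusted p = 0.0087, and adjusted p = 0.554 with an estimated correlation). The neurogenic factor Neurog2 reached 4.31 ± 1.75 FPKM and Fabp7 24.6 ± 4.00. Fatty acid oxidation and respiration genes rose in 21 of 31 cases, or 22 with 1 lower adjusted over the list alone (median 0.50, adjusted p = 1.7e-06, and adjusted p = 0.0278 with an estimated correlation). Fabp3, the cardiac fatty acid binding protein gene, rose 7.24-fold to 284 ± 35.9 FPKM. Glycolysis genes fell in 19 of 29 cases (median -0.53, adjusted p = 6.8e-05, and adjusted p = 0.39 with an estimated correlation), and cell cycle genes in 19 of 32 with 1 higher (median -0.27, adjusted p = 0.000191, and adjusted p = 0.134 with an estimated correlation). Of 20 p53 genes, 13 rose (median 0.59, adjusted p = 4.6e-05, and adjusted p = 0.146 with an estimated correlation), including Cdkn1a, 5.01-fold to 113 ± 4.25 FPKM. Notch genes fell in 15 of 26 cases and 3 rose (median -0.56, adjusted p = 0.00145, and adjusted p = 0.39 with an estimated correlation). Formative genes fell in 9 of 15 cases and 1 rose (median -0.39, adjusted p = 0.0412, and adjusted p = 0.568 with an estimated correlation), and trophoblast genes rose in 8 of 14 and 1 fell (median 0.73, adjusted p = 0.00472, and adjusted p = 0.179 with an estimated correlation). T fell 3.71-fold to 10.6 ± 3.33 FPKM (adjusted p = 0.00158) and the Nodal co-receptor gene Cfc1 13.0-fold, while Pou5f1 measured 19.3 ± 6.78 FPKM (adjusted p = 0.7) and without wild type d10 replicate 1 its log2 change turned from 0.13 to -0.09. The formative list was not called without wild type d6 replicate 3 (adjusted p = 0.0528), without d10 replicate 3 (0.109) or after quantile normalization (0.0751), whereas the skeletal myogenic list, at 0.054, was called without d10 replicate 3 (0.0242) or Carma3xpA/+ d0 replicate 1 (0.038). The neural crest list was called in none of the 3 wild type steps and none of the 4 genotype comparisons, with adjusted p of 0.765, 0.223 and 0.189 over the steps. In all, 6486 genes changed, 3295 higher and 3191 lower (3091 and 3965 after quantile normalization). Without replicate 1 of Carma3xpA/+ at d0 the blood (0.0809), endothelial (0.0633) and fatty acid oxidation (0.0809) lists of this step, and the pluripotency list of the step before (0.0517), no longer passed with an estimated correlation.

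**Figure D1:**
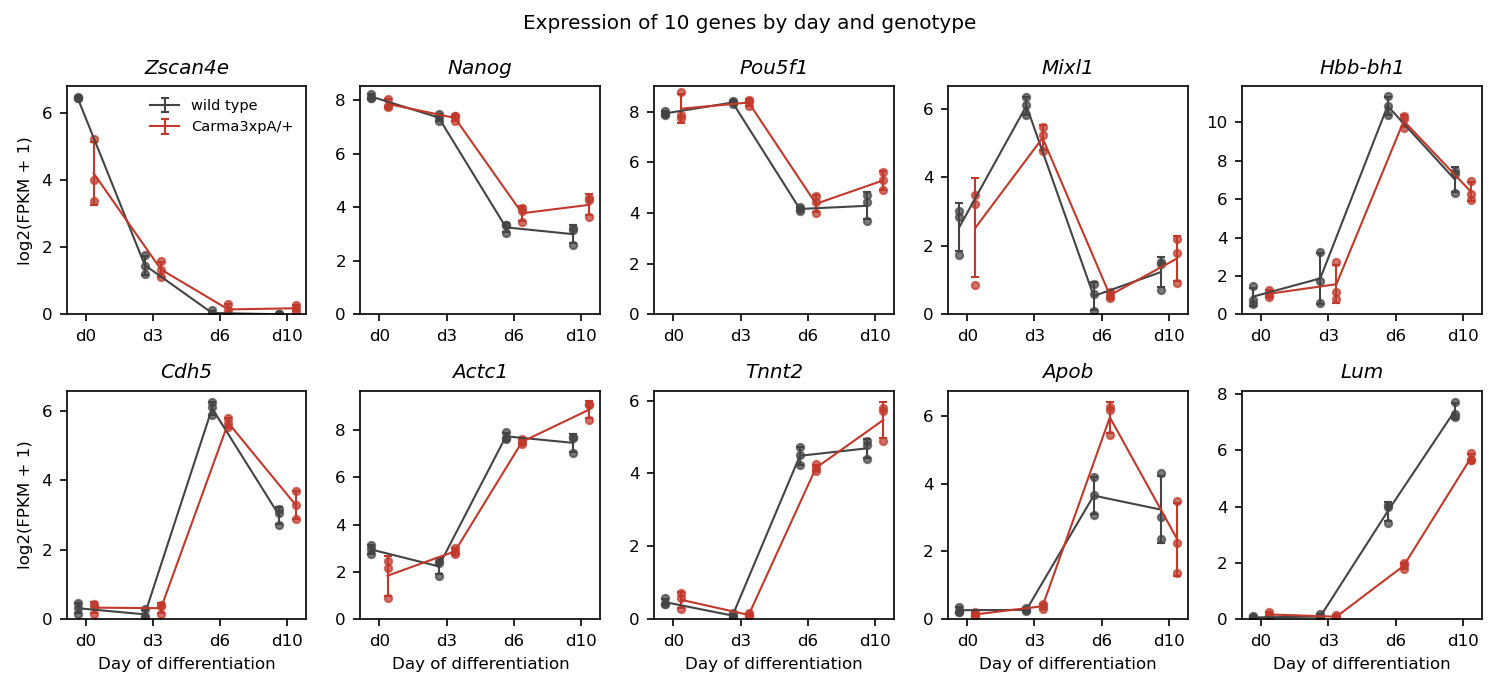
FPKM of 10 genes over d0, d3, d6 and d10 in wild type and Carma3xpA/+ cells, drawn as log2(FPKM + 1) against day, with 1 point per library and lines through the group means (bars: SD on that scale, 3 libraries). Zscan4e, Nanog and Pou5f1 were highest at d0 or d3, Mixl1 at d3, Hbb-bh1 and Cdh5 at d6, and Actc1 at d10 was 478 ± 114 FPKM in Carma3xpA/+ against 179 ± 43.6 in wild type.

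The genotype comparisons ask what the Carma insertion changed on each day. A regional pattern accompanied all of them. Genes on chromosome 11 were higher in Carma3xpA/+ as a whole: over 675 genes with a mean of 5 FPKM or more, the median log2 difference from wild type of the same day was between 0.24 and 0.34 in 11 Carma3xpA/+ libraries. It was 0.06 in replicate 1 of d0 and between -0.03 and 0.02 in the 12 wild type libraries. Medians of the other autosomes lay between -0.12 and 0.05 in those 11 libraries and between -0.23 and 0.16 in replicate 1 of d0, so its chromosome 11 did not stand out. Chromosome 8 was lower in all 9 Carma3xpA/+ libraries of d3, d6 and d10 (-0.12 to -0.05), with 35, 39 and 48 of its genes called lower and 9, 12 and 15 higher, and the cause was not tested. Chromosome 11 held 8.11% of the genes tested, but 18.9% of those called higher at d0, 40.0% at d3, 39.0% at d6 and 37.6% at d10. Replicate 1 of Carma3xpA/+ at d0 also lacked Y-linked transcripts: Ddx3y was at 0.0744 FPKM against 12.8 and 17.4 in replicates 2 and 3. Xist was not analysed here. Genotype and cell line are the same split of these libraries, so a difference between genotypes is also one between the lines.

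**Figure D2:**
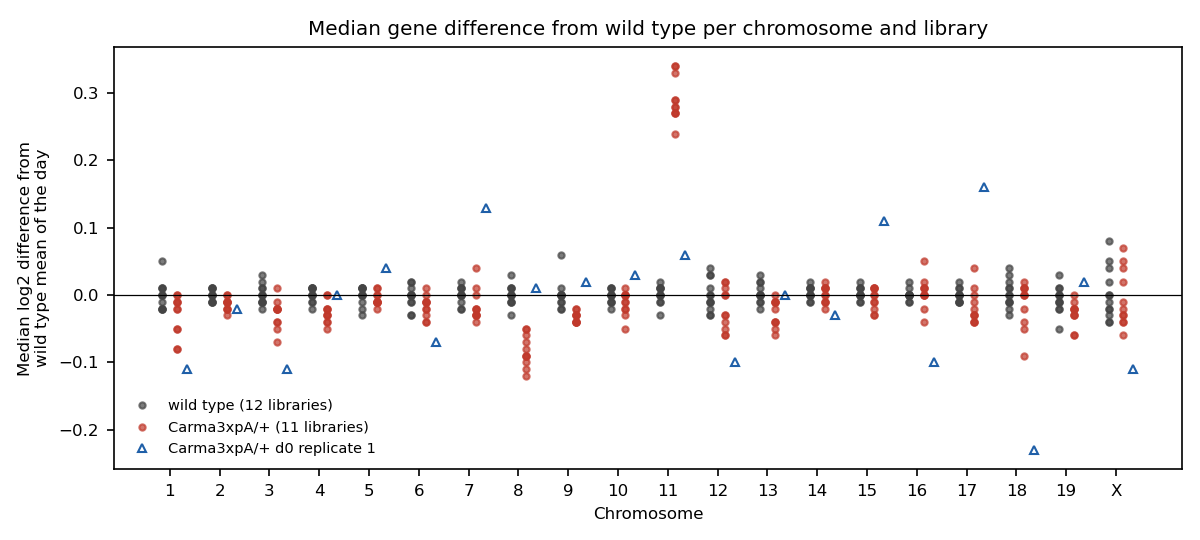
Median log2 difference from the wild type mean of the same day (vertical axis) for each chromosome (horizontal axis), with 1 point per library, over genes with a mean of 5 FPKM or more. Chromosome 11 lies between 0.24 and 0.34 in 11 Carma3xpA/+ libraries, at 0.06 in replicate 1 of d0, and near 0 in wild type.

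At d0, genes of the 2-cell-like state were lower in Carma3xpA/+. Of 19 genes of the 2-cell-like state, 17 were lower, 18 adjusted over the list alone (median log2 difference -1.21, adjusted p = 3.7e-14, and adjusted p = 0.787 with an estimated correlation). Zscan4e measured 20.4 ± 14.4 against 87.5 ± 1.05 FPKM, a 4.30-fold difference (adjusted p = 2.7e-05), and Zscan4b, Zscan4f and Zscan4c were lower 4.01-fold, 2.63-fold and 2.53-fold (without Carma3xpA/+ replicate 1 the 4 folds were 7.16, 7.34, 5.30 and 5.28). The spread came from replicate 1, where Zscan4c was at 71.3 FPKM against 18.5 and 14.9 in the other replicates and 85.7 to 90.6 in wild type. Rhox5, an X-linked homeobox gene, was 4.12-fold higher (256 ± 36.5 against 62.1 ± 8.46, adjusted p = 4.7e-07), Tuba3a 3.56-fold and the sterol pathway gene Fdps 2.88-fold. Spink1 (31.2 ± 22.0 against 4.41 ± 0.959) and Mum1l1 (9.14 ± 5.76 against 1.53 ± 0.103) were higher with a wide spread. Glycolysis genes were higher in 7 of 29 cases (median 0.14, adjusted p = 0.0107, and adjusted p = 0.979 with an estimated correlation), including the lactate dehydrogenase gene Ldha, 1.55-fold. Of 25 cardiac progenitor regulators 3 were higher, Tbx20, Smarcd3 and Hopx, the last 2.99-fold (median 0.18, adjusted p = 0.0212, and adjusted p = 0.979 with an estimated correlation). Replication-dependent histone genes were higher in 3 of 18 cases, Hist1h2ad, Hist1h2ae and Hist1h1c (median 0.39, adjusted p = 0.0107, and adjusted p = 0.979 with an estimated correlation). Pou5f1 (291 ± 122 against 243 ± 14.6) and Nanog (231 ± 27.4 against 278 ± 19.2) were not called (adjusted p = 0.646 and 0.303), and the log2 difference of Pou5f1, 0.19, was -0.13 after quantile normalization. Rbpj was lower, 20.2 ± 4.79 against 31.8 ± 2.93 FPKM (adjusted p = 0.00322), as were T (20.5 ± 13.7 against 42.9 ± 12.7, adjusted p = 0.0386), Actc1 (2.29-fold, adjusted p = 0.0116) and Zbed6 (adjusted p = 0.0221). Ddx3y had a log2 difference of -1.07 (adjusted p = 0.218), which was 0.22 without replicate 1 of Carma3xpA/+ and -1.83, then called (adjusted p = 0.0325), without its replicate 3.

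At d0 limma called 2516 genes, 1274 higher and 1242 lower (1260 and 1445 with median-of-ratios scaling), with 241 of the higher genes on chromosome 11. A fit of only these 6 libraries called 4 genes, Gm45717, Gadd45g, Fam25c and Rhox5, of which all but Rhox5 were chosen after their values were seen, so that no other gene call named for d0 held in that fit, whereas the 4 list calls did. Without replicate 1 of Carma3xpA/+, 2279 genes were called (1435 higher, 844 lower) and 1533 of the calls above were kept in the same direction. Its omission also ended the calls of T (adjusted p = 0.229), Actc1 (0.0511), Zbed6 (0.108), the histone list (0.733) and the glycolysis list (0.061), turned Pou5f1 to a log2 difference of -0.14, and brought calls of the pluripotency (0.00646), p53 (0.0174) and Y-linked lists (0.0174), while the 2-cell-like list then passed with an estimated correlation (adjusted p = 0.000214). The cardiac regulator list was not called without replicates 2 (0.206) or 3 (0.139) of Carma3xpA/+ or wild type replicate 3 (0.0766), and the fatty acid oxidation list, at 0.264, was called without replicate 2 of Carma3xpA/+ (0.0412). Quantile normalization ended the glycolysis call (0.412). Without wild type replicate 1, 1338 genes were called and T (0.134), Mum1l1 (0.0513) and Zbed6 (0.0696) were lost. Without wild type replicate 2, 1404 were called and T (0.126) and Actc1 (0.0527) were lost. Zbed6 was also lost without wild type replicate 3 (0.0579) and Mum1l1 without replicate 3 of Carma3xpA/+ (0.0643), and with a pseudocount of 0.1 Zbed6 was at 0.0683.

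At d3 the pluripotency, germ cell and Y-linked lists were higher in Carma3xpA/+ at the preset correlation only. Of 28 pluripotency genes 8 were higher, 10 adjusted over the list alone (median log2 difference 0.23, adjusted p = 0.000221, and adjusted p = 0.436 with an estimated correlation). Dppa3, which protects maternal methylation marks, measured 38.2 ± 4.07 against 15.0 ± 0.604 FPKM, and Rex2 was 2.20-fold higher. Of 14 germ cell genes 4 were higher, Stk31, Sycp1, Dmrt1 and Tex19.1, and 6 adjusted over the list alone (median 0.37, adjusted p = 1.3e-05, and adjusted p = 0.135 with an estimated correlation). Tex19.1, on chromosome 11, was 5.00-fold higher (4.94 ± 0.290 FPKM in wild type, adjusted p = 1.0e-09) and Dmrt1 2.90-fold. Of 6 Y-linked genes 3 were higher, Kdm5d, Uba1y and Zfy1 (median 0.70, adjusted p = 0.00114, and adjusted p = 0.617 with an estimated correlation), with Uba1y at 17.1 ± 0.474 against 1.86 ± 0.130 FPKM and Zfy1 4.44-fold higher. Outside the lists, the interferon-induced GTPase gene Gbp3 (8.45-fold) and, on the X chromosome, Klhl13 (131 ± 11.3 against 21.9 ± 3.51), Usp26 (6.64-fold) and Pnma5 (6.42-fold) were higher. Of 20 p53 genes 3 were higher, Ccng1 (on chromosome 11), Plk2 and Cdkn1a, the last 1.54-fold, and 5 adjusted over the list alone (median 0.16, adjusted p = 0.00159, and adjusted p = 0.464 with an estimated correlation). The streak and early mesoderm list was lower as a whole with 0 of 24 members called by limma (median -0.28, adjusted p = 0.02, and adjusted p = 0.982 with an estimated correlation). That call was lost without wild type replicates 2 (0.0637) or 3 (0.278), without Carma3xpA/+ replicate 1 (0.326) and with a pseudocount of 0.1 (0.0602). T measured 59.9 ± 12.4 against 92.5 ± 10.4 FPKM (adjusted p = 0.496), Mesp1 13.7 ± 5.35 against 18.3 ± 10.3 (log2 difference -0.28, adjusted p = 0.831, and 0.07 or 0.03 without wild type replicate 3 or Carma3xpA/+ replicate 1), and Pou5f1 327 ± 26.9 against 327 ± 12.3. Myh6 was higher at a low level (2.73 ± 0.186 against 1.16 ± 0.187, adjusted p = 0.00837). The imprinted growth factor adaptor gene Grb10 was 2.81-fold lower (9.29 ± 0.593 against 26.1 ± 2.41) although it lies on chromosome 11. Elovl5 (2.32-fold), Senp6 (2.39-fold) and Tmem30a (2.10-fold), all on chromosome 9, were lower, as was Zbed6 (2.32 ± 3.17 against 8.79 ± 0.459).

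At d3, 865 genes were called, 607 higher and 258 lower, with 243 of the higher genes on chromosome 11, and leaving that chromosome out gave 568. The count was 1563 without replicate 1 of Carma3xpA/+ at d0, which enters the shared estimate of the spread, 529 without wild type replicate 2, 519 without wild type replicate 3 and 519 without replicate 1 of Carma3xpA/+. The call of Zbed6 (adjusted p = 0.0457) was lost without any 1 of 5 libraries, wild type replicates 1, 2 and 3 and Carma3xpA/+ replicates 1 and 3, at adjusted p of 0.113, 0.112, 0.123, 0.218 and 0.211, as well as with a pseudocount of 0.1 (0.0593) or quantile normalization (0.0548). With a pseudocount of 0.1 Uba1y (adjusted p = 0.0703) and Zfy1 (0.122) were also not called. A fit of only the 6 libraries of d3 called 2271 genes and not Zbed6 (0.0824). The skeletal myogenic list, at 0.0545, was called without Carma3xpA/+ replicates 2 (0.0492) or 3 (0.0416).

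At d6 the endoderm list was higher in Carma3xpA/+ and the blood, sarcomere, fibroblast and neuroectoderm lists were lower, at the preset correlation only. Of 28 endoderm genes 10 were higher and 1, Foxa1, lower, with 18 and 1 adjusted over the list alone (median log2 difference 1.17, adjusted p = 1.5e-10, and adjusted p = 0.355 with an estimated correlation). Cubn and Amn, the parts of the visceral endoderm uptake receptor, were 10.3-fold (11.5 ± 1.90 against 1.11 ± 0.471 FPKM, adjusted p = 1.4e-06) and 7.48-fold higher. The apolipoprotein genes Apoc2 (59.6 ± 19.5 against 9.48 ± 4.16) and Apob (63.4 ± 18.7 against 12.2 ± 4.89) were 6.29-fold and 5.21-fold higher. Blood genes were lower in 10 of 23 cases, 13 adjusted over the list alone (median -0.73, adjusted p = 4.2e-12, and adjusted p = 0.0566 with an estimated correlation). The heme synthesis gene Alas2 was 2.46-fold lower and Gfi1b 2.40-fold. Sarcomere genes were lower in 11 of 32 cases, 14 adjusted over the list alone (median -0.35, adjusted p = 1.1e-09, and adjusted p = 0.355 with an estimated correlation), including Cox6a2, 2.29-fold. Tnnt2 (16.8 ± 1.13 against 21.6 ± 3.85), Myh6 (28.5 ± 2.09 against 33.3 ± 2.94), Actc1 (181 ± 13.0 against 214 ± 23.9) and Nkx2-5 (8.89 ± 2.14 against 9.57 ± 1.00) were not called (adjusted p = 0.352, 0.58, 0.745 and 0.798). Fibroblast genes were lower in 7 of 23 cases and 1, Twist2, higher, with 9 and 1 adjusted over the list alone (median -0.20, adjusted p = 0.000185, and adjusted p = 0.362 with an estimated correlation), with the matrix genes Lum 4.92-fold and Postn 4.18-fold lower. Neuroectoderm genes were lower in 6 of 20 cases (median -0.15, adjusted p = 0.000212, and adjusted p = 0.413 with an estimated correlation). Outside the lists, Tbx4 on chromosome 11 (28.3 ± 9.01 against 4.57 ± 1.21) and Slc13a4 (25.6 ± 2.54 against 4.88 ± 1.14) were higher. The chemokine gene Ccl3 was 8.26-fold lower, the homeobox gene Nkx6-1 5.74-fold and the interferon-stimulated gene Isg15 5.41-fold. Isg15 (adjusted p = 0.0321) lost its call without wild type replicates 2 (0.142) or 3 (0.152) or without Carma3xpA/+ replicates 1 (0.0925), 2 (0.0594) or 3 (0.108). With a pseudocount of 0.1 Alas2 (0.0773) and Cox6a2 (0.157) were not called, and in a fit of only these 6 libraries Isg15 (0.0604), Gfi1b (0.0892) and Cox6a2 (0.0581) were not. Without Carma3xpA/+ replicate 2 the log2 difference of Nkx2-5 turned from -0.11 to 0.06.

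Pluripotency genes were again higher at d6 in 7 of 28 cases, 9 adjusted over the list alone (median 0.27, adjusted p = 2.3e-06, and adjusted p = 0.233 with an estimated correlation), with Tbx3 3.18-fold and Dppa3 2.39-fold higher, while Nanog was 12.8 ± 2.50 against 8.52 ± 1.11 FPKM (adjusted p = 0.0815, and 0.0431 without Carma3xpA/+ replicate 3). Germ cell genes were higher in 3 of 14 cases, Sycp3, Tex19.1 and Stk31, and 5 adjusted over the list alone (adjusted p = 0.000485). So were p53 genes in 6 of 20 cases with 1, Plk2, lower, 7 and 1 adjusted over the list alone (adjusted p = 0.00714), and Y-linked genes in 2 of 6, Zfy1 and Kdm5d, 3 adjusted over the list alone (adjusted p = 0.00319). With an estimated correlation these adjusted p were 0.233, 0.413 and 0.436. Glycolysis genes had a median of 0.19 with 2 of 29 higher, the glucose transporter genes Slc2a3 and Slc2a1 (adjusted p = 0.00309). Imprinted genes had a median of 0.24 (adjusted p = 0.0164), with Dlk1, Phlda2, Rtl1 and Zrsr1 (chromosome 11) higher and Nnat and Grb10 lower of 19, 6 and 2 adjusted over the list alone. Trophoblast genes had a median of 0.25 (adjusted p = 0.042), with Plac1 and Tfap2c higher of 14, 3 with 1 lower adjusted over the list alone. With an estimated correlation their adjusted p were 0.616, 0.616 and 0.413. Notch genes (Lfng, Hes5 and Dll4 of 26 lower, median -0.08, adjusted p = 0.0401) and histone genes (0 of 18 called by limma, 6 lower adjusted over the list alone, median -0.43, adjusted p = 2.2e-05) were lower, with adjusted p of 0.616 and 0.436 with an estimated correlation. The Notch call was lost without wild type d6 replicate 1 (0.0778), Carma3xpA/+ d6 replicate 3 (0.0531) or Carma3xpA/+ d0 replicate 1 (0.0599), and after quantile normalization (0.0624). The trophoblast call was lost without wild type replicate 3 (0.131) or Carma3xpA/+ replicates 1 (0.073) or 3 (0.0922), and the glycolysis call without Carma3xpA/+ replicates 1 (0.136) or 3 (0.111). With a pseudocount of 0.1 the Notch (0.0823), imprinted (0.0631) and trophoblast (0.0631) lists were not called. Endothelial genes, not called at 0.103, were called without wild type replicate 3 (0.00487) or Carma3xpA/+ replicate 2 (0.0398), BMP targets (0.0949) without wild type replicate 2 (0.0381) and unfolded protein response genes (0.952) without wild type replicate 1 (0.0291). At d6, 1040 genes were called, 575 higher and 465 lower, 224 of the higher ones on chromosome 11. Without that d0 library 1709 were called, without wild type d6 replicate 2 the count was 592, and without Carma3xpA/+ d6 replicates 1 or 3 it was 600 or 642.

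At d10 the sarcomere, endothelial and pluripotency lists were higher in Carma3xpA/+ and the fibroblast and neuroectoderm lists lower, at the preset correlation only. Of 32 sarcomere genes 21 were higher, 24 with 1 lower adjusted over the list alone (median log2 difference 0.70, adjusted p = 6.6e-16, and adjusted p = 0.108 with an estimated correlation). Actc1 measured 478 ± 114 against 179 ± 43.6 FPKM (2.66-fold, adjusted p = 0.00241) and Tnnt2 45.0 ± 14.3 against 25.1 ± 4.40 (adjusted p = 0.00803). Myh6 was 59.6 ± 20.3 against 34.2 ± 6.20 (adjusted p = 0.00988). Myl7, Tcap and Myl4, all on chromosome 11, were 2.83-fold, 2.98-fold and 2.63-fold higher. Without chromosome 11 members the list's median was 0.55. Cardiac progenitor regulators were higher in 4 of 25 cases, Smyd1, Gata5, Tbx5 and Nkx2-5, and 5 with 1 lower adjusted over the list alone (median 0.13, adjusted p = 0.0204, and adjusted p = 0.54 with an estimated correlation). Nkx2-5 was at 5.35 ± 1.43 against 2.90 ± 0.541 (adjusted p = 0.00992), whereas Isl1 measured 5.30 ± 1.71 against 3.96 ± 0.719 (adjusted p = 0.356). Endothelial genes were higher in 11 of 24 cases, 14 adjusted over the list alone (median 0.35, adjusted p = 9.6e-08, and adjusted p = 0.108 with an estimated correlation), with Plvap 2.08-fold (adjusted p = 0.00939) and Sox18 2.00-fold. Pluripotency genes were higher in 13 of 28 cases, 15 with 3 lower adjusted over the list alone (median 0.43, adjusted p = 9.6e-08, and adjusted p = 0.108 with an estimated correlation). Pou5f1 measured 38.8 ± 9.76 against 19.3 ± 6.78 FPKM (adjusted p = 0.0108), Nanog was 2.31-fold and Dppa3 3.18-fold higher, and T was 16.6 ± 4.39 against 10.6 ± 3.33 (adjusted p = 0.404). Germ cell genes were higher in 5 of 14 cases, Mael, Tex19.1, Dmrt1, Dazl and, 9.07-fold, the meiosis gene Stra8, and 8 adjusted over the list alone (median 0.37, adjusted p = 7.6e-06, and adjusted p = 0.108 with an estimated correlation). Fibroblast genes were lower in 10 of 23 cases and 3, Prrx1, Twist2 and Tcf21, higher, with 14 and 3 adjusted over the list alone (median -0.65, adjusted p = 9.3e-06, and adjusted p = 0.175 with an estimated correlation). Lum was 52.7 ± 5.01 against 172 ± 35.0 FPKM and Dcn 3.15-fold lower. Neuroectoderm genes were lower in 9 of 20 cases (median -0.48, adjusted p = 6.8e-07, and adjusted p = 0.175 with an estimated correlation), with Neurog2 6.48-fold and Hes5 4.54-fold lower (15.5-fold and 8.26-fold without Carma3xpA/+ replicate 1). Without wild type replicate 3 the calls of Pou5f1 (adjusted p = 0.0924), Nkx2-5 (0.0727), Tnnt2 (0.0646), Myh6 (0.0789) and Plvap (0.067) were lost, and without replicate 3 of Carma3xpA/+ those of Pou5f1 (0.0748), Nkx2-5 (0.0704), Tnnt2 (0.0646) and Myh6 (0.0651). The cardiac regulator list was not called without replicate 1 of Carma3xpA/+ (0.0788), and with a pseudocount of 0.1 Nkx2-5 (0.156), Tnnt2 (0.0792) and Tcap (0.0656) were not.

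At d10 the complement genes C1qa (0.635 ± 0.217 against 8.57 ± 0.198 FPKM), C1qb (6.94-fold) and C1qc (9.75-fold), typical of macrophages, were lower in Carma3xpA/+. So were the placental prolactin family genes Prl2b1 (14.6-fold) and Prl3b1 (10.8-fold) and the trophoblast gene Tpbpa (6.07-fold), and the trophoblast list was lower in 3 of 14 cases, Wnt7b, Prl2c2 and Tpbpa, with Plac1 higher (median -0.21, adjusted p = 0.0235, and adjusted p = 0.252 with an estimated correlation). Tuba3a (12.6 ± 1.61 against 1.94 ± 0.701), Fmr1nb (3.08-fold) and the chromosome 11 genes Calcoco2 (4.75-fold) and Upp1 (3.09-fold) were higher. Glycolysis genes were higher in 7 of 29 cases, 8 adjusted over the list alone (adjusted p = 1.7e-05), and cell cycle genes in 5 of 32, Birc5, Cdc6, Aurka, Aurkb and Ccnb2, and 9 adjusted over the list alone (adjusted p = 0.0012). Smooth muscle genes were higher in 4 of 17 cases, Cnn1, Sh3bgr, Myh11 and Kcnmb1, and 7 adjusted over the list alone (adjusted p = 0.00224), and formative genes in 3 of 15, Nodal, Dnmt3b and Zic2, and 4 adjusted over the list alone (adjusted p = 0.000984). With an estimated correlation these adjusted p were 0.288, 0.168, 0.252 and 0.269. Fatty acid oxidation genes had a median of 0.13 (adjusted p = 0.00676), with Acadvl and Atp5a1 higher and Cpt1a lower of 31, 4 and 1 adjusted over the list alone. Skeletal myogenic genes had a median of 0.29 (adjusted p = 0.0311), with Mylpf, Acta1, Myog and Myh3 higher and Tnni2 and Tnnt3 lower of 8. BMP targets (only Nodal higher of 22 by limma, adjusted p = 0.0311) and streak genes (only Dll1 called of 24, lower, and 0 adjusted over the list alone, adjusted p = 0.0306) had medians of 0.19 and 0.37. With an estimated correlation their adjusted p were 0.175, 0.168, 0.54 and 0.645. Birc5, Cdc6, Aurkb, Kcnmb1, Acadvl and Myh3 lie on chromosome 11, and without it the cell cycle, smooth muscle, fatty acid oxidation and skeletal lists were still called (adjusted p = 0.00576, 0.00196, 0.003 and 0.0458). Unfolded protein response genes were lower in 2 of 23 cases, Atf5 and Slc7a5 (median -0.20, adjusted p = 0.0495, and adjusted p = 0.54 with an estimated correlation). That call was lost without any 1 of wild type replicates 1, 2 and 3 (0.0563, 0.0872 and 0.0527), Carma3xpA/+ replicate 1 (0.724) or Carma3xpA/+ d0 replicate 1 (0.0659), without chromosome 11 (0.0602), and with median-of-ratios scaling (0.0657). The streak, skeletal and BMP calls were lost without wild type replicate 3 (0.0634, 0.0527 and 0.0634) or Carma3xpA/+ replicate 1 (0.121, 0.0566 and 0.125), and the streak call without its replicate 3 (0.0946). The trophoblast call was lost without Carma3xpA/+ replicate 1 (0.158) and the fatty acid oxidation call without replicate 2 (0.0809). Quantile normalization ended the skeletal (0.0757), BMP (0.064), cell cycle (0.0757) and fatty acid oxidation (0.0885) calls. The endoderm list, not called at 0.723, was called without Carma3xpA/+ replicate 1 (0.00118) or 2 (0.000689), the stress gene list (0.101) without replicate 1 (0.0111), Wnt targets (0.122) without replicate 2 (0.0103), and Y-linked genes (0.12) without Carma3xpA/+ d0 replicate 1 (0.0457).

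At d10, 1453 genes were called, 662 higher and 791 lower (858 and 718 after quantile normalization), with 249 of the higher genes on chromosome 11. The count was 2391 without replicate 1 of Carma3xpA/+ at d0, 2355 without replicate 1 of Carma3xpA/+ at d10, 910 without its replicate 3 and 856 without wild type replicate 3, while a fit of only these 6 libraries called 703 and none of Pou5f1 (adjusted p = 0.109), Nanog (0.0529), Nkx2-5 (0.111), Tnnt2 (0.149), Myh6 (0.188) and Tcap (0.113). Replicates 1 and 2 of Carma3xpA/+ at d10 correlated at 0.9712, 1 and 3 at 0.9846 and 2 and 3 at 0.989, and Tnnt2 was at 28.6 FPKM in replicate 2 against 51.9 and 54.5 in the others. Replicate 2 also had the highest summed FPKM of all libraries, 306848, and the fewest genes at 1 FPKM at d10, 11321 against 11672 and 11921 in replicates 3 and 1.

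**Figure D3:**
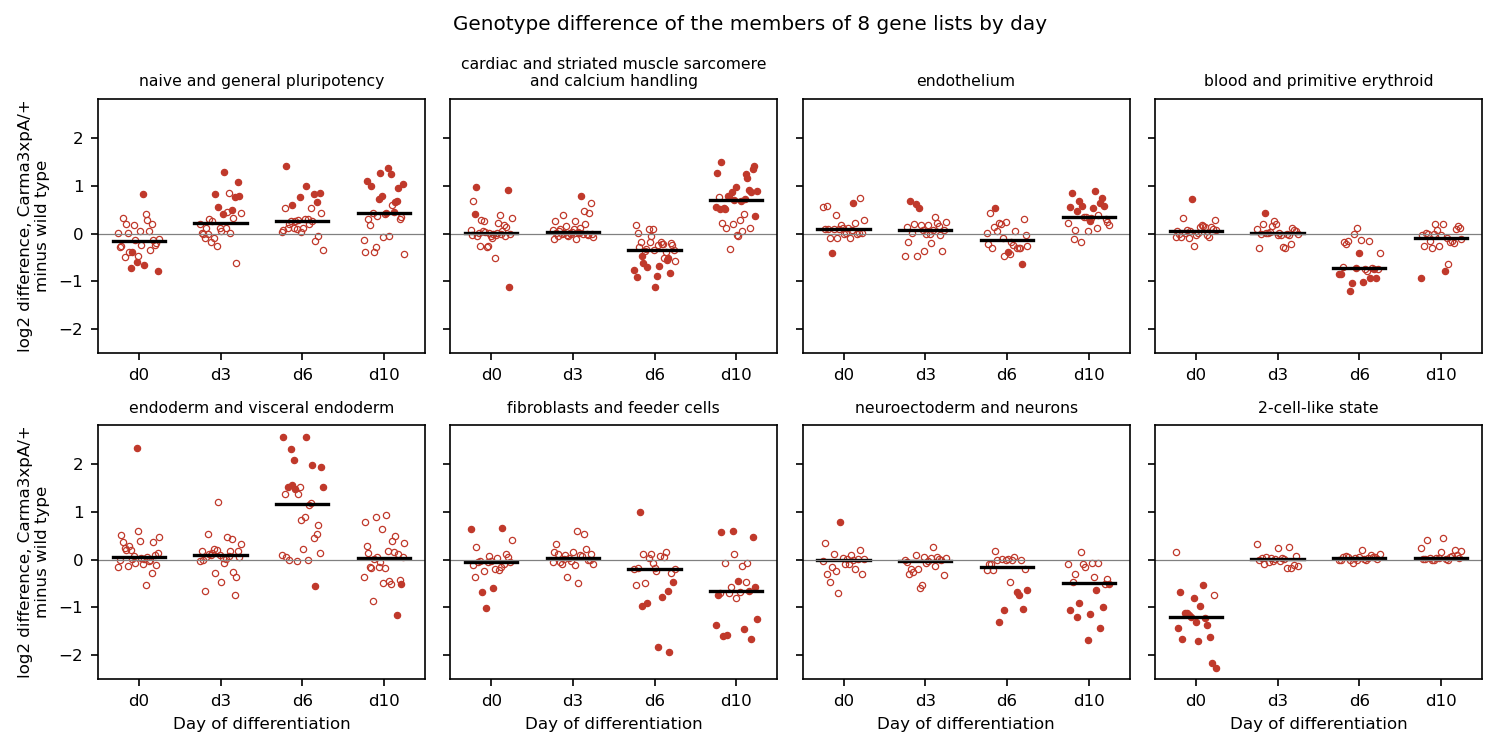
Log2 difference between Carma3xpA/+ and wild type (vertical axis) at d0, d3, d6 and d10 (horizontal axis) for the tested members of 8 gene lists, with filled points for called genes and a bar at the list's median. The sarcomere list had a median of -0.35 at d6 and 0.70 at d10, and the 2-cell-like list a median of -1.21 at d0.

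Whether the genotype difference itself changed from d0 was tested with an interaction term. At d3 the genes of the 2-cell-like state led: 10 of 19 had a higher genotype difference than at d0, 18 adjusted over the list alone (median 1.19, adjusted p = 7.0e-15, and adjusted p = 0.271 with an estimated correlation). Zscan4e was at 1.55 ± 0.418 FPKM in Carma3xpA/+ and 1.80 ± 0.554 in wild type at d3, and its term was 2.13 ± 0.39 (SE, log2, adjusted p = 0.00404). For Zscan4b the term was 2.07 ± 0.40 and for Tex19.1 1.97 ± 0.16. The d3 terms of Cer1 (-1.84 ± 0.51, adjusted p = 0.0482), Acat3 (-1.71 ± 0.39, adjusted p = 0.0206) and Fdft1 (-1.62 ± 0.39, adjusted p = 0.0252) were negative. At d6 the visceral endoderm genes Cubn (2.66 ± 0.34), Apoc2 (2.58 ± 0.64) and Apob (2.44 ± 0.61) had the largest positive terms, and Lum (-2.04 ± 0.20), Lgals9 (-1.90 ± 0.30) and Stmn2 (-1.85 ± 0.28) the most negative ones among named genes. Endoderm genes had higher terms in 8 of 28 cases, 10 adjusted over the list alone (median 0.86, adjusted p = 0.000729, and adjusted p = 0.561 with an estimated correlation). Terms were lower in 9 of 23 blood genes, 12 adjusted over the list alone (median -0.76, adjusted p = 4.1e-08, and adjusted p = 0.26 with an estimated correlation), and in 8 of 32 sarcomere genes, 13 adjusted over the list alone (median -0.44, adjusted p = 5.5e-07, and adjusted p = 0.386 with an estimated correlation). At d10 the skeletal actin gene Acta1 (2.55 ± 0.41, adjusted p = 0.000544) and Actc1 (2.52 ± 0.41, adjusted p = 0.000577) led, and sarcomere genes had higher terms in 10 of 32 cases, 16 adjusted over the list alone (median 0.52, adjusted p = 6.5e-09, and adjusted p = 0.265 with an estimated correlation). Prl2b1 (-2.99 ± 0.22), C1qa (-2.63 ± 0.10) and C1qb (-2.59 ± 0.20) had the most negative terms among named genes, and 7 of 20 neuroectoderm genes had lower ones, 10 adjusted over the list alone (median -0.61, adjusted p = 2.2e-05, and adjusted p = 0.283 with an estimated correlation). The d10 term of Zscan4e, 2.44 ± 0.39 (adjusted p = 0.00048), also mostly restates d0: the gene was listed at 0 in wild type and at 0.199 FPKM or less in Carma3xpA/+.

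At d3, 485 genes differed from d0 in their genotype difference (277 higher, 208 lower), at d6 1339 (666 higher, 673 lower, or 699 and 661 with median-of-ratios scaling) and at d10 836 (339 higher, 497 lower, or 543 and 535 after quantile normalization). Of 28 lists, 8, 15 and 12 were called on the same terms at the preset correlation, and camera called 0, 0 and 0 with an estimated one (smallest adjusted p = 0.152, 0.26 and 0.0842). With median-of-ratios scaling the d3 split was 339 higher and 163 lower of 502. All these terms share the d0 groups, and so replicate 1 of Carma3xpA/+ at d0. Without it 996, 1528 and 1397 genes were called, and for Actc1 at d10 the term became 2.04 (adjusted p = 7.8e-05). The d3 count was 210 and 258 without wild type d0 replicates 1 and 2, and 1265 without Carma3xpA/+ d0 replicate 2. It was 191 and 215 without wild type d3 replicates 2 and 3, and 216, 225 and 320 without Carma3xpA/+ d3 replicates 1, 2 and 3. At d6 it was 759 and 747 without wild type d0 replicates 1 and 2, 825 without wild type d6 replicate 2, 2390 without Carma3xpA/+ d0 replicate 2 and 755 without Carma3xpA/+ d6 replicate 1. Cer1 was still called without wild type d3 replicate 1 or Carma3xpA/+ d0 replicate 1 and lost its call without any 1 of the other 10 libraries, at adjusted p between 0.0547 and 0.135. At d3 Acat3 lost its call without wild type d3 replicates 2 (adjusted p = 0.0542) or 3 (0.0514) or Carma3xpA/+ d3 replicates 1 (0.0651) or 2 (0.0614). Fdft1 lost it without wild type d0 replicates 1 (0.079) or 2 (0.056), wild type d3 replicates 1 (0.0594) or 2 (0.0738), or Carma3xpA/+ d3 replicates 1 (0.0718) or 3 (0.0689). With a pseudocount of 0.1 the d3 terms of Zscan4e (0.058) and Zscan4b (0.057) and the d6 term of Apoc2 (0.0628) were not called.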

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

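The tests of chromosome 11 windows, of replicate 1 of Carma3xpA/+ at d0, and of the chromosome 11 members and the other cell types for the sarcomere list were chosen after the results were seen, whereas those of GC content, of scaling and of other splits of the samples were not.

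Chromosome 11 genes were higher in 11 of 12 Carma3xpA/+ libraries. Matching them to genes of other chromosomes on GC content, length and expression left a difference of at least 0.29 (log2) at d3, d6 and d10, which argues against those properties as the whole cause. A gain of only a part of the chromosome or a few strong genes is argued against by 10 Mb windows, of which none had a median at or below 0 on those days and the lowest was 0.15. An extra copy of the chromosome in these cells may account for the pattern: the highest window median was 0.45, below the 0.58 that 3 copies against 2 would give in every cell, and at d3, d6 and d10 no other autosome had a genotype difference with a median above 0.04. Whether part of the cells carry it, or whether the cassette is involved, was not tested, and the genotype is confounded with the cell line.

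Replicate 1 of Carma3xpA/+ at d0 stood apart from replicates 2 and 3, with 1101 genes off by 2-fold or more. Its deviation followed transcript length (Spearman rho = -0.37 across genes, which are not independent replicates), so RNA quality may explain part of it, but length, GC content and expression took up 19.3% of the variance and the Y-linked genes stayed at a median of -2.93 after that trend was removed, from -3.32 before, whereas its chromosome 11 median relative to replicates 2 and 3 went from -0.40 to -0.21. Ddx3y and Eif2s3y were at most 0.00997 of the lowest wild type library, but as low against replicates 2 and 3. They cannot show or exclude a wild type library. In cells without a Y chromosome and the higher chromosome 11 values the listed Y-linked genes would be below 0.1 of the other replicates' mean. This held for 5 of 5, but these genes prompted the idea, so it stays open. A first form of that test took in pseudoautosomal Erdr1 (37.0 FPKM against 47.7 and 32.2). Erdr1 went against it, and the test was cut to the fixed list. The library also lacked the lower chromosome 9 values below (median 0.26).

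The sarcomere list was higher in Carma3xpA/+ at d10, with a median of 0.70. Without its chromosome 11 members the median was 0.55, so these members are not the whole cause. Under the other scalings the list stayed at least 0.66 above the median of all genes. A lower share of every other cell type would lower all their markers. Yet limma called 11 of 24 endothelial (median 0.35) and 13 of 28 pluripotency genes higher and 0 lower. With an estimated correlation these 2 calls and the sarcomere call were lost (adjusted p = 0.108 each). An effect of the Carma insertion on muscle genes, more muscle cells, or a cell line difference, chromosome 11 included, stays open. So does a lower share of some types: some fibroblast and neuroectoderm genes were lower.

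From d0 to d3 the genotype difference itself changed for 485 genes. Of 100 splits by genotype within each day 5 gave as many, the real one included, and the highest other gave 2387, so chance is not excluded. At d6 it changed for 1339 genes, and 1 of 100 splits, the real one, gave as many, the lowest share possible (highest other 798). At d10 it changed for 836 genes, and 6 of 100 splits gave as many (highest other 2510), so chance is not excluded. The other splits with as many calls, 4 at d3 and 5 at d10, kept the genotypes apart on 1 of the 2 days. They carry the genotype difference of that day. Among splits that mixed the genotypes on both days the highest counts were 16, 5 and 11. The terms at d3 were Zscan4e 2.13, Zscan4b 2.07, Tex19.1 1.97, Cer1 -1.84, Acat3 -1.71 and Fdft1 -1.62. At d6 they were Cubn 2.66, Apoc2 2.58, Apob 2.44, Lum -2.04, Lgals9 -1.90 and Stmn2 -1.85. At d10 they were Acta1 2.55, Actc1 2.52, Zscan4e 2.44, Prl2b1 -2.99, C1qa -2.63 and C1qb -2.59. The Zscan4e terms mostly restate d0.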

How the results depend on the processing

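Leaving out chromosome 11, and leaving out replicate 1 of Carma3xpA/+ at d0 where it is not in the groups compared or together with an estimated correlation, were chosen after the data were seen. The cause of the changes below was not tested unless the alternative's construction shows it. The 3 steps of the wild type series kept their gene counts within 1.5 times under every other setting than the size threshold, and the genotype counts did not. Of 2542 values of 190 named results under alternatives, 2415 kept direction and side of the threshold, 101 were no longer called, 9 became called and 17 changed sign. Of the 101, 55 came from leaving out 1 library, 30 from fitting only the groups compared, 13 from the pseudocount, 2 from the block and 1 from quantile normalization.

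An absolute log2 change of at least 1, a stricter rule by construction, left 1678, 2293 and 1350 genes in the wild type steps, 144, 91, 134 and 160 in the genotype comparisons at d0, d3, d6 and d10, and 108, 280 and 259 in the changes of the genotype difference at d3, d6 and d10. The filter at 5 FPKM, which tests fewer genes, gave 573 at d3, 551 at d6 and 759 at d10, 877 and 357 for the changes at d6 and d10, and 2 lists at d0. Fits of only the groups compared gave 4 genes at d0, 2271 at d3 and 703 at d10, and 171, 433 and 225 for the changes. Sample quality weights gave 6168, 3925, 2328 and 8223 genes at d0, d3, d6 and d10 and 4452, 4254 and 6135 for the changes. A pseudocount of 0.1 gave 518 for the change at d10, and leaving out chromosome 11 gave 568 genes at d3. With the estimated correlation camera called 0, 4 and 3 lists in the wild type steps and 0 at d0, d3, d6 and d10. Without replicate 1 of Carma3xpA/+ at d0 as well it called 5, 3 and 0 lists in the steps, 1 at d0 and 0 at d3, d6 and d10. The transcript table gave 2 called records of the locus at d0, 1 transcript each of Lama5 and Dido1, against 4 genes. Splits into higher and lower that turned with scaling are given with the results.

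Leaving out 1 library gave 6679 to 8193, 7328 to 8778 and 5537 to 7559 genes in the wild type steps. It gave 1338 to 3606 at d0, 519 to 1563 at d3, 592 to 1709 at d6 and 856 to 2391 at d10, and 191 to 1265, 747 to 2390 and 578 to 1397 for the changes. Lists ranged over 15 to 16, 18 to 20 and 13 to 15 in the steps and 3 to 5, 4 to 6, 11 to 15 and 13 to 18 by genotype. The libraries that moved a count by over 1.5 times are named with the results.

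Differences that were not called changed sign, the largest that of Ddx3y at d0. At d3 Pou5f1 went from 0.00 to 0.02 with median-of-ratios scaling and to 0.01, 0.02 and 0.07 without wild type replicates 2 or 3 or Carma3xpA/+ replicate 2 (range without 1 library -0.05 to 0.07). At d0 it went from 0.19 to -0.13 with quantile normalization, -0.08 with quality weights and -0.14 without Carma3xpA/+ replicate 1 (-0.14 to 0.38), and Ddx3y from -1.07 to 0.40 with quality weights (then called, adjusted p = 0.00829) and 0.22 without that replicate (-1.83 to 0.22). Mesp1 at d3 went from -0.28 to 0.07 and 0.03 without wild type replicate 3 or Carma3xpA/+ replicate 1 (-0.83 to 0.07), and Nkx2-5 at d6 from -0.11 to 0.06 without Carma3xpA/+ replicate 2 (-0.26 to 0.06). Between d6 and d10 of the wild type, Myh6 went from 0.03 to -0.15 with quantile normalization and to -0.07 and -0.03 without 1 library (-0.07 to 0.18), and Pou5f1 from 0.13 to -0.09 without wild type d10 replicate 1 (-0.09 to 0.42).

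List calls also changed with settings not named beside the results. Fits of only the groups compared ended those of Wnt targets at d3 and smooth muscle at d10 in the wild type steps (0.0675 and 0.0765), and of skeletal and trophoblast genes at d10 by genotype (0.0729 and 0.0851). Quality weights ended those of formative genes in the d10 step (0.0667), histones at d0 (0.458), Notch at d6 (0.0575) and skeletal, trophoblast and unfolded protein genes at d10 (0.0888, 0.225 and 0.12). With a pseudocount of 0.1 the Wnt call of the d3 step ended (0.0843), and the sarcomere, skeletal and endothelial lists at d3 (0.0157, 0.0079 and 0.0253) and the 2-cell-like list at d10 (0.00655) were called. Quantile normalization brought calls of BMP targets in the d6 step (0.0252) and at d6 (0.0471), pluripotency and cell cycle at d0 (0.0107 and 0.00134) and skeletal genes at d3 (0.00858). Quality weights brought calls of skeletal genes in the d10 step (0.0326), pluripotency and Y-linked genes at d0 (0.00737 and 0.0437) and Wnt targets at d10 (0.0321), and fits of only the groups compared of skeletal genes in the d10 step (0.0481), BMP targets at d6 (0.00672) and the 2-cell-like and Wnt lists at d10 (0.00399 and 0.0448). With quality weights Nanog at d0 (0.0413) and d6 (0.0329), T at d3 (0.0099) and d10 (0.000909), Tnnt2 in the d10 step (0.035) and Pou5f1 in the d3 step (0.00997) were called. Among genes, fits of only the groups compared brought a call of Pou5f1 in the d3 step (0.43, adjusted p = 0.00132) and ended the d3 changes of Zscan4e (0.078), Zscan4b (0.0965), Cer1 (0.175), Acat3 (0.142) and Fdft1 (0.0948).

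Same-numbered replicates were not paired: their correlations lay between -0.17 and 0.2, 0 of 7 comparisons had every pair above 0.1, and 5 of 21 samples correlated best with their own number, with 0 comparisons in which every sample did. The replicate block gave 7335, 7961 and 6386 genes in the wild type steps, 2313, 831, 991 and 1369 by genotype, and 388, 1235 and 811 for the changes. It gave 16, 18, 14, 4, 5, 14 and 17 lists, the same numbers as without it. It ended the calls of Zbed6 at d3 (0.0594) and of the Cer1 change (0.0526) and no other named call.

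Of 10 splits of 6 samples the share cannot fall under 0.05. The real split called 7416, 8038 and 6486 genes in the wild type steps and 2516, 865, 1040 and 1453 by genotype. The highest others called 0, 1, 1, 266, 2, 14 and 124, so 1 of 10 gave as many each time. At the preset correlation the real split called 16, 18, 14, 4, 5, 14 and 17 lists. The highest others called 17, 19, 15, 13, 7, 10 and 16. As many came from 3, 4, 2, 5, 6, 1 and 1 of 10. Other splits keep part of the real difference, so they cannot measure chance.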

Other observations

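The contrast between d10 and d6, the overlap of days and the stretch of chromosome 9 were chosen after the results were seen, whereas the position between wild type days was planned.

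Some genes were higher in Carma3xpA/+ whatever the day. Of the genes called higher at d3, d6 and d10, 118 were shared by the 3 days, against 1.29 if the lists were independent, and 71 of the 118 were on chromosome 11. Each day had its own wild type libraries. Among those on other chromosomes were Dppa3 (mean log2 difference 1.22), the tudor domain gene Rnf17 (1.03), the tubulin gene Tuba3a (1.80) and the X-linked genes Pnma5 (1.79), Xlr3b (1.80) and Fmr1nb (1.35), picked after their values were seen. Including d0, 71 genes were shared (0.123 if independent), 54 of them on chromosome 11. Genes lower on all 3 later days numbered 19 (0.531 if independent), and with d0 11 (0.0493). Of the 19, 10 were on chromosome 9, among them Senp6 (-1.04), Elovl5 (-0.98) and Slc17a5 (-0.88), and 4 on chromosome 19, while Grb10 (-1.01) was on chromosome 11.

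On chromosome 9, Senp6 and Elovl5 lie close together. Medians of the genotype difference were taken over 540 windows of 2 Mb with at least 5 genes at a mean of 5 FPKM or more. The highest over the genome was 0.68, over 5 X-linked genes from 138 Mb. The lowest was near Senp6 and Elovl5, from 78 Mb (median -0.72 over 6 genes). Over the 9 such genes between 77 and 81 Mb, Gclc, Elovl5, Gsta4, Dppa5a, Ooep, Eef1a1, Cox7a2, Tmem30a and Senp6, library medians lay between -0.89 and -0.54 in 11 Carma3xpA/+ libraries and between -0.14 and 0.06 in wild type, and the median was 0.26 in replicate 1 of Carma3xpA/+ at d0. The other 365 such genes of chromosome 9 had a median of -0.01, and 1 copy in place of 2 would lower the log2 value by 1. limma called 4, 5, 6 and 5 of the 9 genes lower at d0, d3, d6 and d10, and 11, 10, 14 and 12 of all 20 tested there. No explanation of this stretch was tested.

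Between d6 and d10 the genotype difference moved in opposite directions for the sarcomere and endoderm lists, the latter at the preset correlation only. It changed for 565 genes, 202 higher and 363 lower. Sarcomere genes had higher terms in 19 of 32 cases (median 1.09, adjusted p = 3.7e-30, and adjusted p = 0.0495 with an estimated correlation). Endothelial genes followed in 7 of 24 cases (median 0.45, adjusted p = 6.6e-09, and adjusted p = 0.065 with an estimated correlation) and blood genes in 5 of 23 (median 0.39, adjusted p = 1.1e-06, and adjusted p = 0.105 with an estimated correlation). Endoderm genes had lower terms in 6 of 28 cases (median -1.11, adjusted p = 1.5e-08, and adjusted p = 0.383 with an estimated correlation) and trophoblast genes in 4 of 14 (median -0.39, adjusted p = 9.7e-05, and adjusted p = 0.065 with an estimated correlation).

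Carma3xpA/+ samples were also placed on the line between consecutive wild type days, where 0 is the earlier and 1 the later day. They differed from wild type samples by 0.13, -0.06, -0.06 and -0.12 at d0, d3, d6 and d10 (exact permutation p = 0.1, 0.1, 0.1 and 0.2, and 3 against 3 samples cannot give less than 0.1). The genes and the line came from the same wild type libraries, which draws other samples toward the middle, and all 4 differences point that way, so they do not show an earlier or later state.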
